A study of Mus musculus with 12 samples.

How the data were processed

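The 12 libraries came from mouse embryonic fibroblasts (MEFs) with 2 floxed AF10 (Mllt10) alleles, an inducible OSKM cassette of Pou5f1, Sox2, Klf4 and Myc, and rtTA, per the labels. The cells received an adenovirus with Cre recombinase (groups with creAF10 in their name, called AF10-deleted here) or an empty adenovirus (groups with fl in their name), per the labels' protocols. No group without floxed alleles received the Cre virus, so each effect of AF10 deletion below may include an effect of that virus. Reprogramming was started 2 days later with 2 µg/mL doxycycline, in DMSO or in 5 µM SGC0946, an inhibitor of the histone H3 lysine 79 methyltransferase DOT1L. Cells were harvested as MEFs or on day 4 of reprogramming, which gave 6 groups of 2 libraries. MEFs were kept in MEF medium, and reprogramming cells in embryonic stem cell medium with leukemia inhibitory factor on gelatin with DR4 feeder MEFs, per the labels' protocols. Medium, feeder cells and doxycycline therefore all differed between the MEF and the day 4 groups.

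Polyadenylated RNA was made into libraries with the TruSeq RNA kit, per the labels' protocols. Reads were assigned to RefSeq genes of mouse genome build mm9 with RSEM and Bowtie, per the submitters' processing notes, which give no versions or options. The deposited tables hold, per the file headers, RSEM expected counts for 20325 genes. They also hold the deposited TPM values and the deposited FPKM values, both of which RSEM computes from those counts and the transcript lengths. The effective length equalled the length in 100% of the entries. RSEM divides reads that match several genes among them, so values of genes with near-identical copies are uncertain. The total of expected counts was 14602536 to 22800753 per library. The files of 10 libraries hold 25 gene names each that read as dates, while the 2 Day4_creAF10_DMSO files hold none. Genes were therefore matched through their transcript identifiers. No genome of build mm9 was at hand, so no coordinates are given.

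The expected counts were rounded to whole numbers, and genes were kept with edgeR's filterByExpr over the 6 groups, which left 13936 genes. CPM values, the counts scaled to a common library size, used TMM-scaled totals. Tests were made with edgeR 4.0.16 in R 4.3.3: 1 fit over the 12 libraries with a term per group, the quasi-likelihood F test with robust dispersions, and Benjamini-Hochberg adjustment over the genes kept. Genes with an adjusted p under 0.05 were counted as called. The SE of a log2 fold change is its size divided by the square root of F. DESeq2 1.42.0 was run beside it. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

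Replicate numbers 1 and 2 occur in each group. Whether they pair the libraries was checked from the deviations of each library from its group's mean: the correlation across genes was 0.286 to 0.737 over the 15 pairs of groups, from 0.413 to 0.737 within a stage (MEFs or day 4) and from 0.286 to 0.34 across stages. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 4035 to 4780 counts in sum in each replicate 1 library and 8 to 52 in each replicate 2 library. The numbers therefore mark 2 sources of cells of different sex, kept through all 6 groups. The labels do not name these sources. In the first fit the p-values measure the spread between 2 cell preparations, not between many animals. The planned fit with the replicate number as a block took it as the same in both stages. Because the correlation was larger within a stage, a further fit with a replicate block per stage was added after the data had been seen. It is called the paired fit below. Within a stage its p-values measure how alike the changes were in the 2 sources, after the difference between the sources was taken out. The error is largely shared across genes, with a median of 22.4 prior degrees of freedom from other genes against 4 residual ones. For day 4 against MEFs the block per stage also takes out any disagreement between the 2 sources. The paired p-values there do not measure how alike the changes were. In no comparison do the paired p-values measure the spread between many animals. Counts of calls of the paired fit stand beside those of the first fit, since it changed most of them. Most genes named for AF10 deletion and all of those named for the interactions carry values of the paired fit, and the first fit called 0 genes for AF10 deletion within a stage and treatment and for the interactions. Named genes were the strongest calls per comparison and the strongest called members of each list, by the fixed rule, and the same rule was applied to the paired fit; genes named from that fit alone were therefore chosen after their values had been seen. Not every gene that the rule picks is named. The biological coefficient of variation was 0.148 in the first fit, 0.0906 with the replicate block and 0.0549 in the paired fit.

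The fits were tried on simulated counts for SGC0946 against DMSO in fl cells, with 13825 genes and 3 draws. Without a block, 14.7% of changed genes were called at a log2 change of 0.5, 72.7% at 1, 89.3% at 2 and 95.3% at 3, with 0% false calls. With the paired fit these shares were 52%, 88.7%, 100% and 98%, with 6.1% false calls. The simulated counts had the same replicate difference in both stages, and a dispersion set by the expression level alone. The shares therefore do not cover replicate differences that vary by stage, for which the paired fit was added.

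The 26 gene lists were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes, adjusted over 208 tests (26 lists in 8 comparisons; both comparisons of day 4 with MEFs were left out). With a correlation estimated from the data, none of the 18 list calls held. Of 588 distinct genes in the lists, 5 were not found in the files. The log2 fold changes of genes without a count in a group are no more than bounds; a floor of 3 counts over the group was used for them, which covers counting error only.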

Results

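RNA was sequenced from mouse embryonic fibroblasts (MEFs) and from such cells on day 4 of reprogramming, in 12 libraries, 2 in each of 6 groups. MEF_fl had intact floxed alleles of AF10, the product of Mllt10 and a partner of the histone methyltransferase DOT1L, and MEF_creAF10 had received Cre recombinase to delete it. On day 4, fl and AF10-deleted cells were grown in DMSO (Day4_fl_DMSO and Day4_creAF10_DMSO) or in the DOT1L inhibitor SGC0946 (Day4_fl_SGC and Day4_creAF10_SGC). The expected counts of replicates 1 and 2 summed to 18711382 and 17477675 in MEF_fl and to 16258109 and 22800753 in MEF_creAF10. On day 4 in DMSO they summed to 16834238 and 21109210 in fl cells and to 14645732 and 17292985 in AF10-deleted cells. In SGC0946 the sums were 14728087 and 14602536 in fl cells and 17531504 and 15135736 in AF10-deleted cells. The first principal component of log2 CPM held 77% of the variance and parted MEFs from day 4. The next held 7.7% and parted the replicate numbers. On the one after, with 5.2%, the day 4 libraries lay in the order fl in DMSO (31.8 and 22.3), AF10-deleted in DMSO (15.1 and 6.87), then fl in SGC0946 (-15.2 and -19.1) and AF10-deleted in SGC0946 (-16.2 and -23.9).

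Mllt10 reads were lower in every AF10-deleted library than in the fl library of the same replicate number, and most of them were still present. The level was 44.2 ± 1.62 CPM (SD, n = 2) in MEF_fl and 34.9 ± 0.651 in MEF_creAF10. On day 4 it was 58.3 ± 4.25 CPM in fl cells and 43.0 ± 1.74 in AF10-deleted cells in DMSO, and 54.9 ± 1.09 and 41.1 ± 0.793 in SGC0946. AF10-deleted replicates 1 and 2 kept 82.1% and 75.9% of the fl level in MEFs, 72.1% and 75.5% on day 4 in DMSO, and 77% and 72.8% in SGC0946. Mllt10 fell in the paired fit in MEFs, in DMSO and in SGC0946 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0322, 0.001 and 0.0178), while the first fit gave adjusted p = 0.704, 0.537 and 1. The files hold 1 transcript of Mllt10, so reads of the deleted part cannot be told from reads of the rest, and these counts do not measure how much AF10 protein was lost. Dot1l itself, the catalytic subunit, had 55.0 CPM in MEF_fl, with a log2 change of -0.056 ± 0.12 (SE) after deletion. On day 4 it had 56.3, 56.2, 64.8 and 63.9 CPM in Day4_fl_DMSO, Day4_creAF10_DMSO, Day4_fl_SGC and Day4_creAF10_SGC.

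**Figure D1:**
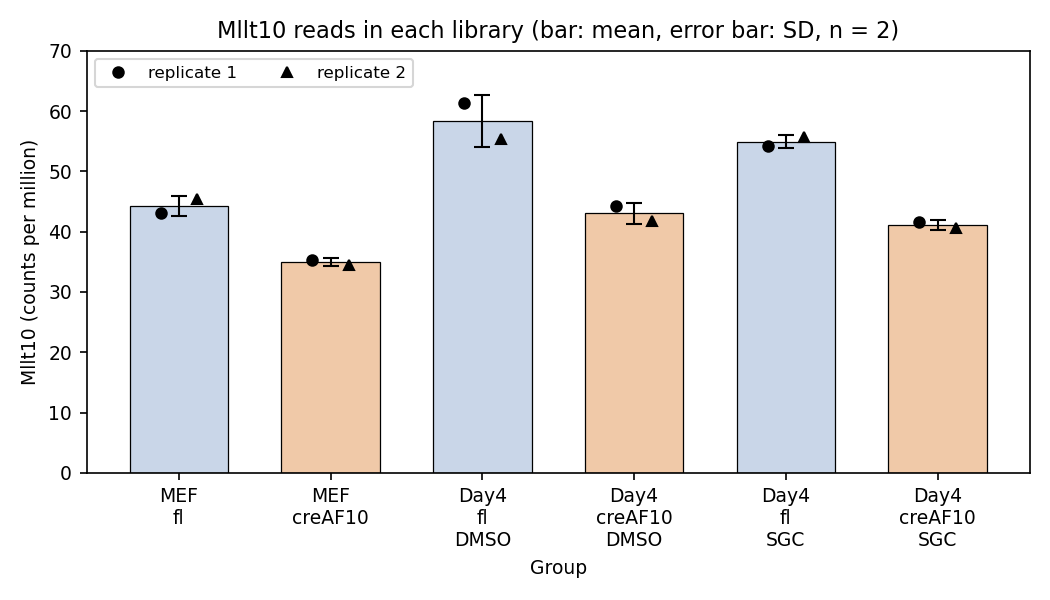
Mllt10 in CPM in each library by group, with bars for the mean of 2 libraries, error bars for the SD and points for the replicates. Each AF10-deleted group lies below its fl group, at 34.9 against 44.2 CPM in MEFs and 43.0 against 58.3 CPM on day 4 in DMSO.

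Day 4 was compared with MEFs in fl cells to describe what 4 days of reprogramming, with the change of medium and the feeder cells that came with it, did to expression. Of 29 fibroblast and matrix genes 24 fell and 1 rose, 3 of the 4 reprogramming factors rose, and of 20 pluripotency genes 10 rose and 4 fell. Postn, a matrix protein of fibroblasts, had a log2 change of -5.14 ± 0.36 (SE, n = 2 per group), the collagen cross-linking enzyme Lox -2.92 ± 0.12, the collagen gene Col5a2 -2.22 ± 0.10 and Zeb2, a transcription factor of the mesenchymal state, -1.74 ± 0.12. Of the 4 transgene factors, Pou5f1 rose by 7.31 ± 0.27, Myc by 4.32 ± 0.18 and Sox2 by 3.92 ± 0.22, while Klf4, already at 186 CPM in MEF_fl, moved by 0.15 ± 0.15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.426, and 0.047 in the paired fit), or by -0.01 without MEF_fl replicate 2, and its log2 change within replicates 1 and 2 was -0.07 and 0.38. L1td1, an RNA-binding protein of pluripotent cells, went from 0.21 to 57.8 CPM, and Cdh1, the epithelial cadherin, rose by 4.17 ± 0.39, while Cdh3 fell (-4.33 ± 0.27). Of the 13936 genes tested, 3588 rose and 3659 fell (4728 and 4774 in the paired fit), and in AF10-deleted cells 3833 rose and 3832 fell (4955 and 4843). Paired fit calls between day 4 and MEFs, here and in the lists below, leave out how unlike the change was in the 2 sources.

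Among the other lists, 13 of 19 mesenchymal regulators and 14 of 20 contractile and TGF-beta response genes fell in fl cells, and 1 of each rose. Of 18 epithelial genes 10 rose and 1 fell. Of 36 proliferation genes 35 rose and 1 fell, with Mki67 at 1.58 ± 0.12 and the replication helicase subunit Mcm7 at 1.24 ± 0.083. Interferon response genes were the list with the lowest median, -4.27, and 33 of 34 fell. Examples were Ifit1 (-6.38 ± 0.42) and Usp18 (-5.64 ± 0.19). Of 29 genes of cholesterol and fatty acid synthesis 26 fell, among them Sqle (-1.67 ± 0.23), and 15 of 20 glycolysis genes rose, among them the glucose transporter gene Slc2a3 (2.00 ± 0.21). In the DOT1L complex 5 of 9 genes rose, including Mllt3 (1.82 ± 0.20), and in the super elongation complex 3 of 17 rose and 6 fell. Of the 39 Hox and Meis genes 2 rose and 9 fell, against 5 and 25 in the paired fit. Of 26 p53 targets 9 rose and 1 fell (11 and 5 in the paired fit), and of 28 genes of senescence and secretory inflammation 9 rose and 6 fell (15 and 9), with Igfbp5 at -3.72 ± 0.16. Unfolded protein and stress genes fell in 14 of 22 cases and rose in 2, replication-dependent histones fell in 4 of 15 and rose in 1, and immediate early genes fell in 4 of 14 and rose in 1, against 11 and 2 in the paired fit.

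Among lists of other cell types, 9 of 16 macrophage and blood genes rose and 0 fell. Laptm5, a lysosomal protein of blood cells, went from 0.804 to 43.6 CPM. Of 16 chondrocyte and osteoblast genes 4 rose and 12 fell, 9 of 17 neural genes and 6 of 13 genes of skeletal and cardiac muscle fell, and none of either rose (paired fit, 3 and 0). Of 8 endothelial genes 2 rose and 3 fell, of 8 keratinocyte genes 3 rose and 1 fell (3 and 3 in the paired fit), and of 8 adipocyte genes 1 rose and 2 fell (1 and 5). The 4 sex-linked genes gave 0 calls, against 3 higher in the paired fit. Their sum went from 283 CPM in MEF_fl to 275 in Day4_fl_DMSO in replicate 1. In replicate 2 it went from 1.09 to 2.38 CPM, or from 18 to 52 counts, so the sum rose only in a source with few such reads. Adjusted over the list alone, the counts were the same except for the mesenchymal regulators (14 lower), epithelial and pluripotency genes (11 higher each), Hox and Meis genes (1 higher and 5 lower), p53 targets (8 and 0), interferon response (34 lower), histones (0 and 1) and unfolded protein and stress (3 and 15). For AF10-deleted cells, Postn fell (-5.46 ± 0.36) between MEFs and day 4, and Pou5f1 rose by 7.44 ± 0.28, Myc by 3.97 ± 0.17, Sox2 by 3.60 ± 0.22, L1td1 by 8.35 ± 0.22, Laptm5 by 5.98 ± 0.48 and Mllt3 by 1.78 ± 0.20.

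AF10 deletion was examined in MEFs, before reprogramming. Interferon response genes were lower together: 34 of 34 had a negative log2 change, 33 of them in both replicate pairs, with a median of -0.57. Oas1a, a sensor of double-stranded RNA, had 81.2 CPM in MEF_fl and 41.8 in MEF_creAF10 (paired fit, -0.96 ± 0.088 on the log2 scale, SE, n = 2 per group), the membrane protein Bst2 went from 716 ± 53.6 to 469 ± 23.7 CPM (SD), and the GTPase Gbp2 stood at -1.03 ± 0.091. Further interferon-inducible genes outside the list fell in the paired fit, namely Ifi47 (-1.01 ± 0.13) and Sp110 (-1.06 ± 0.19). Gm4902, Phf11 and Tgtp1 did so as well, at -1.81 ± 0.21, -1.07 ± 0.15 and -1.17 ± 0.18, but they share sequence with near-identical copies and are uncertain, as Oas1a and Oas3 (-1.01 ± 0.22) may be. Mt1, a metal-binding protein, was the gene with the lowest paired p that rose, by 2.40 ± 0.091, from 91.2 to 466 CPM. The matrix protein gene Ctgf (0.40 ± 0.071), Nr4a1 (0.46 ± 0.084), Spry4 (0.59 ± 0.12), the chemokine gene Cxcl1 (0.58 ± 0.13), Plk2 (0.26 ± 0.066) and Rps29 (0.48 ± 0.086, with pseudogene copies) also rose in that fit. The macrophage and blood list had a median of 0.25 here, with 10 of 16 genes positive.

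In MEFs edgeR's first fit called 0 genes, with 300 at an unadjusted p under 0.05 where 697 would be expected by chance, and DESeq2 called 1 higher and 19 lower. Here and below, a count under 697 is no sign that an effect was absent. The first fit keeps the difference between the 2 sources of cells in its error term. The paired fit takes that difference out, and there 968 genes had an unadjusted p under 0.05. With the replicate block 0 rose and 6 fell, and in the paired fit 17 rose and 117 fell. Of the interferon genes 0 were called in the first fit, 23 fell adjusted over the list alone, and 26 fell in the paired fit. The list passed camera (adjusted p = 1.24e-36), and missed the threshold with an adjusted p = 0.0646 with an estimated correlation. No other list passed in MEFs. The epithelial list, for one, had 8 of 18 genes positive, a median of -0.11 (-0.02 with Cldn3, which had 0 counts in MEF_creAF10, at its bound) and a mean of -0.18, against a test direction of up.

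On day 4 in DMSO, AF10-deleted cells, which kept 72.1% and 75.5% of the fl level of Mllt10 reads, were compared with fl cells under the reprogramming factors. Of the fixed lists, 4 of 18 epithelial genes, 10 of 14 immediate early genes and 10 of 28 genes of senescence and secretory inflammation rose in the paired fit, 1 of the last fell, and 3 of the 4 reprogramming factors fell, while the first fit called 0 of these. The protease inhibitor gene Spint1 had a log2 change of 1.04 ± 0.17 (paired fit, SE, n = 2 per group), Cdh1 of 0.71 ± 0.11 and the tight junction gene Cldn3 of 1.00 ± 0.22. Of the senescence and secretory inflammation list, the chemokine Ccl2 went from 33.7 ± 0.593 to 66.7 ± 6.2 CPM (SD), with the matrix protease Mmp3 at 0.64 ± 0.077 and the adhesion molecule Icam1 at 0.59 ± 0.084. All 14 immediate early genes, the first genes switched on by growth signals, were positive, among them Fos (0.74 ± 0.086), Junb (0.62 ± 0.087), Dusp1 (0.52 ± 0.069) and Btg2 (0.46 ± 0.077). Of the transgene factors Pou5f1 (-0.46 ± 0.087), Klf4 (-0.32 ± 0.071) and Sox2 (-0.26 ± 0.076) fell in the paired fit. Of 39 Hox and Meis genes 20 were positive and 19 negative (camera adjusted p = 0.954), 0 were called, adjusted over the list alone or not, and in the paired fit Pbx3 rose (0.29 ± 0.083) and Hoxd12 (-0.75 ± 0.15) and Hoxd13 (-0.33 ± 0.069) fell. Of 19 mesenchymal regulators 15 were negative (camera adjusted p = 0.125), 0 were called, adjusted over the list alone or not, and in the paired fit 1 rose and 3 fell, Osr1 at -0.45 ± 0.096, Tbx15 at -0.27 ± 0.064 and Runx2, the regulator of bone formation, at -0.38 ± 0.090. Of 29 genes of fibroblasts and extracellular matrix 10 were positive and 19 negative (camera adjusted p = 0.56), 0 were called, adjusted over the list alone or not, and in the paired fit 1 rose and 2 fell, Postn (-0.29 ± 0.082) among them. Of 16 chondrocyte and osteoblast genes 12 were positive (camera adjusted p = 0.466), 0 were called, adjusted over the list alone or not, and in the paired fit 3 rose, with Spp1 at 0.61 ± 0.071, and 1 fell, Col11a1 (-0.34 ± 0.078). Col28a1, which is in no list, rose by 1.14 ± 0.14.

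Megf9 fell in the paired fit, at -1.11 ± 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.17e-06, against 0.612 in the first fit and 0.0426 with the replicate block). Lnpep (-0.66 ± 0.083), the chloride transporter gene Clcn5 (-0.69 ± 0.12), the cell cycle kinase gene Cdk6 (-0.71 ± 0.17) and the DOT1L complex member Tbl1x (-0.24 ± 0.073) also fell, and Bex1 (1.10 ± 0.18), the epidermal regulator Trp63 (0.48 ± 0.10) and the fatty acid carrier Fabp4 (0.65 ± 0.13) rose. Macrophage and blood genes had a median of -0.38, and Emr1 of that list fell (-1.14 ± 0.35) in the paired fit.

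In this comparison edgeR's first fit called 0 genes, with 988 at an unadjusted p under 0.05 (697 by chance), and DESeq2 called 9 higher and 4 lower. With the block 0 rose and 1 fell, and in the paired fit 469 rose and 470 fell. Of the 18 epithelial genes (median 0.47) 0 were called, 1 rose adjusted over the list alone and 4 rose in the paired fit, and camera gave an adjusted p = 0.00481, with an adjusted p = 0.477 with an estimated correlation. Of the 14 immediate early genes 0 were called, 0 adjusted over the list alone and 10 in the paired fit, and camera gave an adjusted p = 0.0245, with an adjusted p = 1 with an estimated correlation. Fos varied between replicates more than between groups, at 143 ± 112 CPM in fl and 225 ± 140 in AF10-deleted cells, with log2 changes of 0.97 and 0.54 within replicates 1 and 2, and Dusp1 of 0.47 and 0.56. Leaving out 1 library without a block sets 1 replicate against the mean of both, so here and below the value shifts by the difference between replicates too: without Day4_creAF10_DMSO replicate 2 the first fit put Fos at -0.19 and Dusp1 at -0.04. Within replicates 1 and 2 the list medians were 0.50 and 0.29 for epithelial and 0.44 and 0.51 for immediate early genes. Both list calls were lost without Day4_fl_DMSO replicate 1 (camera adjusted p = 0.135 for epithelial and 0.736 for immediate early genes) and without Day4_creAF10_DMSO replicate 2 (0.0674 and 0.895). Of 28 genes of senescence and secretory inflammation 10 rose and 1 fell in the paired fit, where camera gave an adjusted p = 0.000489 (0.0542 without the block), with an adjusted p = 0.202 with an estimated correlation.

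SGC0946 was compared with DMSO on day 4 in fl cells to show the effect of blocking DOT1L's catalytic activity. Of 18 epithelial genes 4 rose in the first fit and 14 in the paired fit, and of 39 Hox and Meis genes 1 fell in the first fit, against 15 lower and 1 higher in the paired fit. The epithelial surface protein Epcam rose by 2.54 ± 0.41 on the log2 scale (SE, n = 2 per group), Spint1 by 1.79 ± 0.25 and Spint2 by 1.14 ± 0.18. Cdh1 (1.43 ± 0.11) and Trp63 (1.18 ± 0.10) rose in the paired fit. Hoxd12 fell from 8.46 ± 1.4 to 1.54 ± 0.426 CPM (SD), a change of -2.45 ± 0.36, and the limb and kidney factor Osr1 (-1.31 ± 0.21), Tbx15 (-0.56 ± 0.068), Runx2 (-0.78 ± 0.12) and Nfix (-0.86 ± 0.11) fell. Hoxd11 (-1.32 ± 0.17) and Hoxd13 (-0.54 ± 0.070) did so in the paired fit. Among secreted proteins, the iron carrier Lcn2 rose by 1.57 ± 0.24, while Igfbp5, a binding protein of insulin-like growth factors, went from 345 ± 14.9 to 174 ± 13 CPM, and the matrix protein Abi3bp fell (-0.93 ± 0.14). Mmp3 (0.94 ± 0.077) and Spp1 (1.00 ± 0.072) rose in the paired fit.

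Further genes that rose with SGC0946 were Col28a1 (2.10 ± 0.30), the cartilage collagen gene Col9a2 (2.00 ± 0.31), Bex1 (2.03 ± 0.24), Bzrap1 (2.12 ± 0.30), Susd1 (2.10 ± 0.24), Mrvi1 (2.09 ± 0.32), Fabp4 (1.40 ± 0.25) and Klf2 (1.02 ± 0.15), and Chodl (2.80 ± 0.21) did so in the paired fit. The RNA-binding protein Igf2bp1 (48.9 to 24.4 CPM), the cell cycle inhibitor Cdkn2c (-0.97 ± 0.18) and the fatty acid elongase Elovl6 (-0.38 ± 0.072) fell. In the paired fit Pou5f1 (-0.35 ± 0.087) and Klf4 (-0.25 ± 0.071) fell, as did the interferon gene Ifit1 (-1.09 ± 0.16) and the macrophage gene Lyz2 (-1.04 ± 0.25). The median of the macrophage and blood list was -0.57.

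edgeR's first fit called 123 genes higher and 32 lower with SGC0946, of which 79 and 2 differed by more than 2-fold. The fit with the replicate block called 559 and 247, the paired fit 1480 and 990, and DESeq2 218 and 85. With any 1 of the 4 libraries compared left out, the first fit called 1 to 5 genes higher and 0 lower, with 5 when this was Day4_fl_SGC replicate 2. The genes named above that the first fit called lost their calls with each of the 4 left out. Of 18 epithelial genes 4 rose, 9 adjusted over the list alone and 14 in the paired fit. Their median was 1.24, and camera gave an adjusted p = 1.41e-08, and an adjusted p = 0.0646 with an estimated correlation. Of 39 Hox and Meis genes 1 fell, 1 adjusted over the list alone and 15 in the paired fit, where 1 rose. In the list 28 were negative, with a median of -0.40, and camera gave an adjusted p = 0.00775, with an adjusted p = 0.957 with an estimated correlation. Of 28 senescence and secretory inflammation genes 1 rose and 1 fell, 3 and 1 adjusted over the list alone and 17 and 1 in the paired fit, with a camera adjusted p = 0.00368 and an adjusted p = 0.709 with an estimated correlation. Of 34 interferon response genes 0 were called, 5 fell adjusted over the list alone, and 12 fell and 2 rose in the paired fit. Their median was -0.32, with a camera adjusted p = 0.00872 and an adjusted p = 1 with an estimated correlation. Without Day4_fl_DMSO replicate 1 the camera calls of Hox and Meis (adjusted p = 0.299), senescence (0.155) and interferon genes (0.0667) were lost, and without Day4_fl_SGC replicate 2 those of Hox and Meis (0.212) and senescence genes (0.1).

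**Figure D2:**
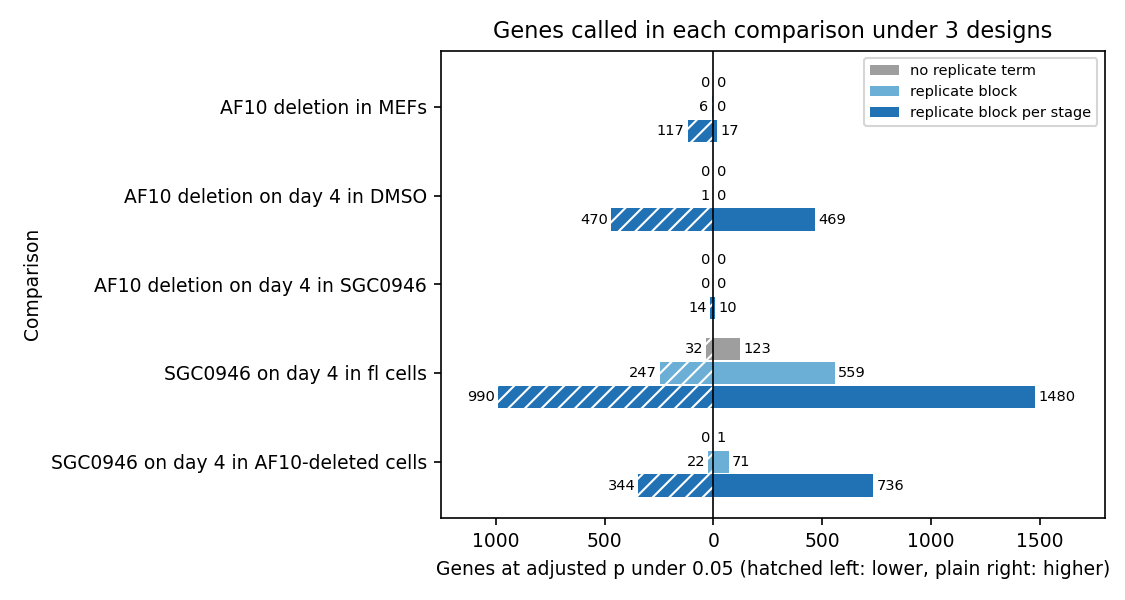
Genes called at an adjusted p under 0.05 in 5 comparisons (vertical axis), as bars to the right for higher and hatched bars to the left for lower, without a replicate term, with the replicate block and with a block per stage. AF10 deletion gave 0 calls without a block, and SGC0946 in fl cells gave 123 higher and 32 lower.

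SGC0946 was also compared with DMSO in AF10-deleted cells, in which most Mllt10 reads were still present. All 18 epithelial genes were positive and 35 of 39 Hox and Meis genes negative, against 16 and 28 in fl cells. In the paired fit the desmosome gene Dsc2 rose by 1.18 ± 0.16 (SE, n = 2 per group), Spint1 by 0.83 ± 0.14, Cdh1 by 0.74 ± 0.10, Trp63 by 0.77 ± 0.099, Mrvi1 by 1.61 ± 0.19, Chodl by 1.89 ± 0.19 and Fabp4 by 0.74 ± 0.12. Hoxd12 (-2.28 ± 0.23), Hoxb3 (-0.98 ± 0.18), Hoxc8 (-0.75 ± 0.14), Osr1 (-0.99 ± 0.11), Tbx15 (-0.33 ± 0.065) and Igfbp5 (-1.10 ± 0.078) fell in that fit. The lactate transporter Slc16a3 (1.43 ± 0.16) and the glucose transporters Slc2a1 (0.33 ± 0.068) and Slc2a3 (0.42 ± 0.089) rose in the same fit, together with the matrix protein Thbs1 (0.45 ± 0.074) and the fibrillin gene Fbn1 (0.42 ± 0.071). Gm10136, an uncertain gene model that can share reads with other loci, went from 31.7 ± 3.01 to 112 ± 16.9 CPM (SD).

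In AF10-deleted cells edgeR's first fit called 1 gene higher and 0 lower, with 955 at an unadjusted p under 0.05 (697 by chance), and DESeq2 called 32 and 15. The replicate block gave 71 and 22 and the paired fit 736 and 344, while with any 1 of the 4 libraries left out the first fit called 0. The median of the 18 epithelial genes was 0.69. Of these 0 were called, 7 rose adjusted over the list alone and 12 rose in the paired fit, and camera gave an adjusted p = 4.01e-08, with an adjusted p = 0.0646 with an estimated correlation. Of 39 Hox and Meis genes 35 were negative, 0 were called, 1 fell adjusted over the list alone and 17 fell in the paired fit, with a camera adjusted p = 7.36e-07 and an adjusted p = 0.709 with an estimated correlation. Of 20 glycolysis genes 0 were called, 3 rose adjusted over the list alone and 4 in the paired fit, with a camera adjusted p = 0.00368 and an adjusted p = 0.709 with an estimated correlation. That call was lost without Day4_creAF10_DMSO replicate 1 (0.0718) and without Day4_creAF10_SGC replicate 1 (0.203). The macrophage and blood list had a median of -0.42.

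**Figure D3:**
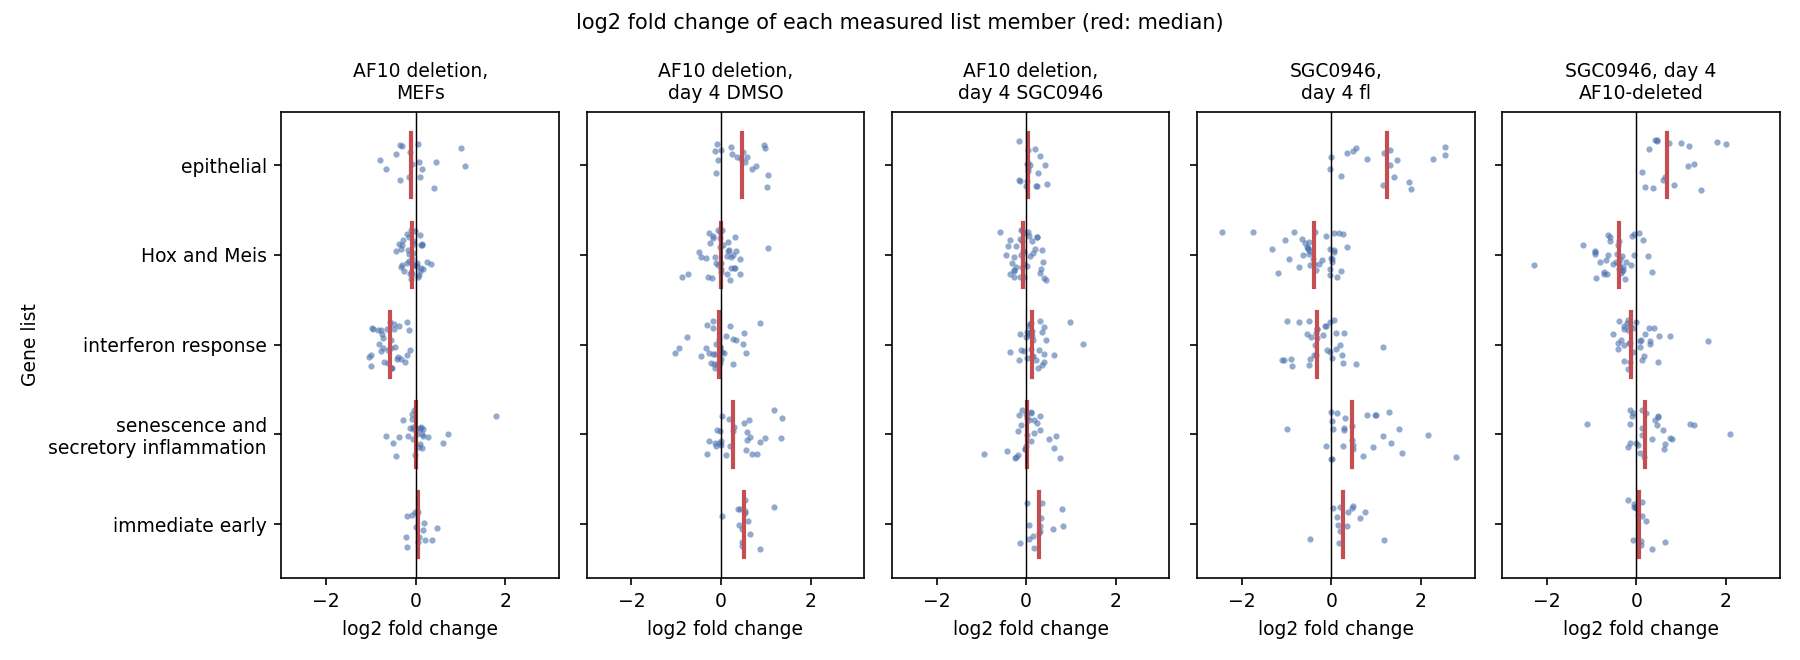
The log2 fold change (horizontal axes) of each measured member of 5 gene lists in 5 comparisons, with a red line at the median; Cldn3, with 0 counts in MEF_creAF10, is left out in MEFs. Interferon response genes lie below 0 with AF10 deletion in MEFs (median -0.57), and epithelial genes lie to the right with SGC0946 (median 1.24 in fl cells and 0.69 in AF10-deleted cells).

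AF10 deletion was also compared within SGC0946 on day 4, which asks how AF10-deleted and fl cells differed in the inhibitor. Fewer genes passed in the paired fit than in DMSO, 24 against 939, while the first fit called 0 in both. In the paired fit Postn (-0.49 ± 0.084, SE, n = 2 per group), Lox (-0.38 ± 0.073), Igfbp5 (-0.43 ± 0.078) and Megf6 (-0.87 ± 0.15) fell. The immediate early gene Nr4a1 rose by 0.58 ± 0.081 and the respiratory chain gene Ndufs4 by 0.42 ± 0.084, and within replicates 1 and 2 Nr4a1 stood at 0.45 and 0.69, though without Day4_creAF10_SGC replicate 2 the first fit put it at -0.01. The ribosomal protein genes Rpl26 (-0.46 ± 0.076) and Rps16 (-0.38 ± 0.075) fell in that fit, but both have pseudogene copies and are uncertain. edgeR's first fit called 0 genes, with 251 at an unadjusted p under 0.05 (697 by chance), DESeq2 called 2 higher and 0 lower, and the paired fit 10 and 14. Interferon response genes were positive in 28 of 34 cases, with a median of 0.13 and 0 called, adjusted over the list alone or not. Camera gave an adjusted p = 0.00432, with an adjusted p = 0.986 with an estimated correlation, and without Day4_creAF10_SGC replicate 2 its direction turned (0.714), while without Day4_fl_SGC replicate 2 the call was lost (0.0623). The list median was -0.01 within replicate 1 and 0.29 within replicate 2. The macrophage and blood list had a median of -0.072.

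Both treatments together were set against untreated fl cells on day 4. Spint1 rose by 1.88 ± 0.25 (SE, n = 2 per group), Mrvi1 by 2.60 ± 0.31 and Trp63 by 1.25 ± 0.24, while Hoxd12 (-3.04 ± 0.38), Osr1 (-1.45 ± 0.21) and Igfbp5 (-1.41 ± 0.15) fell. Mllt10 also fell in the first fit (-0.50 ± 0.082, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0181). The first fit called 179 genes higher and 75 lower, the fit with the replicate block 714 and 402, the paired fit 1714 and 1289, and DESeq2 305 and 184. With any 1 of the 4 libraries compared left out, the first fit called 1 to 5 higher and 0 to 3 lower, with 5 without Day4_creAF10_SGC replicate 2 and 3 without Day4_fl_DMSO replicate 1. Igfbp5 kept its call with 2 of the 4 left out, while Spint1, Mrvi1, Trp63, Hoxd12, Osr1 and Mllt10 lost theirs with each. Of 18 epithelial genes 4 rose, 11 adjusted over the list alone and 15 in the paired fit, with a median of 1.46, a camera adjusted p = 8.61e-09 and an adjusted p = 0.0646 with an estimated correlation. Of 39 Hox and Meis genes 1 fell, 1 adjusted over the list alone and 19 in the paired fit, with a camera adjusted p = 0.00287 and an adjusted p = 0.904 with an estimated correlation. Senescence and secretory inflammation genes (2 of 28 higher and 1 lower, 7 and 1 adjusted over the list alone, 18 and 2 paired) gave a camera adjusted p = 0.00872 and an adjusted p = 0.709 with an estimated correlation. Immediate early genes (0 of 14 called, 2 higher adjusted over the list alone, 10 paired) gave 0.0423 and an adjusted p = 1 with an estimated correlation. The calls of the Hox and Meis, senescence and immediate early lists were lost without Day4_fl_DMSO replicate 1 (camera adjusted p = 0.241, 0.173 and 0.604) and without Day4_creAF10_SGC replicate 2 (0.0648, 0.111 and 0.599).

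Whether AF10 deletion and SGC0946 acted on the same genes was asked from both effects in DMSO-treated or fl cells on day 4. Genes that rose with SGC0946 tended to be higher after AF10 deletion: Spint1 had 4.20, 8.59, 14.5 and 15.4 CPM in Day4_fl_DMSO, Day4_creAF10_DMSO, Day4_fl_SGC and Day4_creAF10_SGC. Igfbp5 went down in the same order, with 345, 278, 174 and 130 CPM. In the paired fit 321 genes rose and 248 fell in both, and 0 were called in opposite directions, while independent lists of these lengths would share 49.8 and 33.4. The first fit shared 0, since it called no gene for the deletion, and the fit with the replicate block shared 1. The comparisons use the same Day4_fl_DMSO libraries, and unchanged groups simulated against such controls had a correlation of log2 changes across genes of 0.436 in 20 draws, against 0.585 observed, and 65.9% of genes with the same sign, against 69.8%. They shared 0 calls, which is no measure for the 569, since these groups held no changes to share. The covariance was 0.104 against 0.0297 simulated, a difference of 0.0739. The simulated genes varied independently, with a dispersion set by the expression level alone. These draws therefore leave out a deviation of the control libraries that many genes share. Genes are not independent replicates, and part of the excess of shared calls may come from the shared controls, which cannot be split. For AF10 deletion in MEFs and on day 4, 6 genes rose and 5 fell in both in the paired fit, against 0.572 and 3.95 for independent lists, 8 went opposite ways, and the correlation was 0.0714. SGC0946 in fl and in AF10-deleted cells, with no library in common, shared 590 higher and 202 lower genes in the paired fit, with 4 opposite, against 78.2 and 24.4 for independent lists and a correlation of 0.484.

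**Figure D4:**
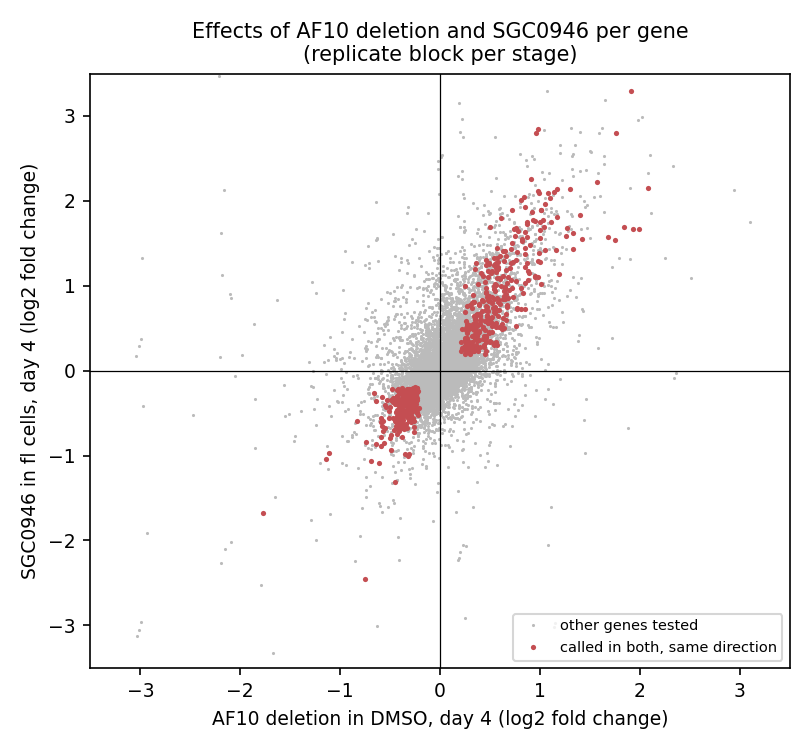
Each point is a gene, by its log2 fold change with AF10 deletion in DMSO (horizontal) and with SGC0946 in fl cells (vertical) on day 4 in the paired fit; 24 genes lie outside the plot. The 569 genes called in both in the same direction, in red, lie in the lower left and upper right.

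The interaction of the deletion and the inhibitor asks whether SGC0946 did less in AF10-deleted cells. Several genes that rose with SGC0946 in the paired fit did so by less after deletion. Their interaction in that fit was -1.13 ± 0.17 (SE, n = 2 per group) for Col28a1, -1.19 ± 0.15 for the secreted protease Htra3, -1.10 ± 0.20 for Lcn2 and -1.21 ± 0.22 for Bex1. It was -0.58 ± 0.11 for Mmp3, -0.49 ± 0.10 for Spp1, -0.69 ± 0.15 for Cdh1, -0.95 ± 0.21 for Spint1 and -0.49 ± 0.096 for Dusp1. For Megf9, which fell with SGC0946 in fl cells in that fit (15.4 to 7.88 CPM), it was 1.20 ± 0.18. For Dusp1 the interaction was -0.43 and -0.55 within replicates 1 and 2, while the first fit gave 0.02 without Day4_fl_SGC replicate 2 and 0.06 without Day4_creAF10_DMSO replicate 2. edgeR's first fit called 0 genes, with 303 at an unadjusted p under 0.05 (697 by chance), DESeq2 1 higher and 1 lower, the fit with the replicate block 1 higher, and the paired fit 10 higher and 45 lower. The 1 call with the replicate block was Rangrf, which 1 library per group carries: it had 4.47 ± 6.32 CPM (SD) in Day4_fl_DMSO and 5.89 ± 8.32 in Day4_creAF10_SGC, each from replicate 2 alone, and 0 counts in the other 2 groups. It is also 1 of the 10 called higher in the paired fit and of the 569 genes shared above, and no other gene of these had a library without a count in each group compared. Interferon response genes had a positive median of 0.23 with 0 called, adjusted over the list alone or not, a camera adjusted p = 0.0207 and an adjusted p = 1 with an estimated correlation. That call was lost without replicate 1 of Day4_fl_DMSO (0.155) or Day4_creAF10_DMSO (0.266) and without replicate 2 of Day4_fl_SGC (0.0884) or Day4_creAF10_SGC (0.921). Senescence and secretory inflammation genes were negative in 25 of 28 cases, with 0 called and 4 lower in the paired fit, where camera gave an adjusted p = 0.000233 (0.0542 in the first fit), with an adjusted p = 0.193 with an estimated correlation. The epithelial list (median -0.37) had a camera adjusted p = 0.0572 in the first fit and 0.0333 in the paired fit, with an adjusted p = 0.368 with an estimated correlation there.

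The effect of the deletion on day 4 in DMSO was also tested against its effect in MEFs. Interferon response genes were lower after deletion in MEFs (median -0.57) but had a median of -0.036 on day 4, and Mt1 was higher in MEFs. As given above, nearly all of these interferon genes were lower on day 4 than in MEFs in fl cells. The medians were therefore taken at unlike levels of expression. In the paired fit the effect on day 4 minus that in MEFs was 0.87 ± 0.099 (SE, n = 2 per group) for Bst2, 1.54 ± 0.18 for Gbp2, 0.77 ± 0.10 for Spp1 and -1.86 ± 0.12 for Mt1. It was 1.58 ± 0.26 for Tgtp1, which has a near-identical copy and is uncertain. For Fos it was 0.73 ± 0.12 and for Dusp1 0.54 ± 0.095 in that fit, with 0.87 and 0.62 for Fos and 0.41 and 0.67 for Dusp1 within replicates 1 and 2, but the first fit gave -0.20 and -0.02 without Day4_creAF10_DMSO replicate 2. edgeR's first fit called 0 genes, with 507 at an unadjusted p under 0.05 (697 by chance), DESeq2 2 higher and 0 lower, and the paired fit 130 and 31. Of 34 interferon response genes 32 were positive, with a median of 0.42, 0 called, 7 higher adjusted over the list alone and 9 in the paired fit. Camera gave an adjusted p = 3.51e-13, with an adjusted p = 0.477 with an estimated correlation. Epithelial genes had a median of 0.54, or 0.47 with Cldn3, which had 0 counts in MEF_creAF10, at its bound, with 0 called, adjusted over the list alone or not, a camera adjusted p = 0.0331 and an adjusted p = 0.709 with an estimated correlation. The epithelial call was lost without replicate 1 of MEF_fl (0.232) or Day4_fl_DMSO (0.181) and without replicate 2 of MEF_creAF10 (0.161) or Day4_creAF10_DMSO (0.131).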

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

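All of the explanation tests below were chosen after the results they weigh had been seen. The differences of effects between groups came from planned contrasts, and those counted in the paired fit rest on the block per stage, which was added later.

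In camera with the preset correlation, but with an adjusted p = 1 with an estimated one, the response to SGC0946 differed between fl and AF10-deleted cells for the interferon response list, with a median log2 difference of 0.23, and the call was lost in 4 of the 8 fits without 1 library (adjusted p = 0.155, 0.266, 0.0884 and 0.921). The paired fit gave 10 genes higher and 45 lower. With the preset correlation the effect of AF10 deletion differed between day 4 and MEFs for the epithelial list, with a median of 0.536 (0.474 with Cldn3 at its bound), and for the interferon response list, with a median of 0.421. In the paired fit that contrast gave 130 genes higher and 31 lower. With an estimated correlation between genes neither of these 2 list differences passed, with adjusted p values from camera of 0.709 and 0.477 in this order.

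Mllt10 reads stayed at 72.1% to 82.1% of the fl level in the 6 pairs of AF10-deleted and fl libraries. RNA of feeder cells in the day 4 libraries cannot be the whole source, since MEF_creAF10, grown without feeders, kept a mean of 79%, above the 74.4 ± 2.3% (SD, n = 4 pairs) of day 4. Reads from the part of Mllt10 that was not deleted (lowest pair, 72.1%) and cells that escaped recombination (highest pair, 82.1%) cannot be told apart, because the files give no reads per exon. How far AF10 function was lost therefore stays open for each comparison of the deletion.

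Interferon response genes were lower in MEF_creAF10 than in MEF_fl. Fewer macrophages or other blood cells are argued against, since that list summed to 11.8 CPM in MEF_fl and 13.2 in MEF_creAF10, while the interferon genes lost 2330 of 7330 CPM. Library scaling is argued against too, since it moves all genes alike, while the list's median differed from that of all genes by -0.563, beyond the members' SD of 0.257. A different response to the Cre and the empty adenovirus stays open, since no group without floxed alleles received the Cre virus. The median on day 4 was -0.036 in cells that had received the same viruses, but nearly all of these genes were lower there than in MEFs. An effect of AF10 itself stays open as well and was not tested apart from the virus.

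AF10 deletion in DMSO moved most genes that responded to SGC0946 the way SGC0946 did. Its median log2 change was 0.201 for the genes higher by the mean response and -0.109 for those lower. Most also responded less in AF10-deleted cells, 1373 of 1859 genes higher by the mean response (73.9%) and 916 of 1280 lower (71.6%). These are not 2 separate findings. A deletion effect that is larger in DMSO than in SGC0946 (medians 0.0263 and -0.0126 there) is the same difference as a smaller response. The Hox and Meis list did not follow, since about as many of its genes were positive as negative with the deletion in DMSO. Its median with SGC0946 was -0.35 and -0.29 within replicates 1 and 2 in fl cells, and -0.49 and -0.43 in AF10-deleted cells. A chance deviation of the shared DMSO libraries, gene by gene, would leave at most as many of the 1080 genes called for SGC0946 in AF10-deleted cells moving the same way with the deletion as the other way, yet 66.9% moved the same way. The choice of genes by their response in fl cells is argued against by the 73.9% above, since those genes were chosen by the mean of both genotypes. Handling that moved the DMSO libraries of 1 genotype along the response to SGC0946 cannot be told apart from the deletion. It would give the same direction in both replicates too (66% and 66.8%). Over all genes 46.7% moved the same way, against 32.9% in unchanged groups simulated gene by gene, which leave out such a shared shift. The Cre virus cannot be told apart from the deletion here either. Another candidate explanation is that AF10 deletion acts in part on the genes that DOT1L inhibition acts on. It is a hypothesis from the same data, which the test in MEFs, which share no library with day 4, left open. Of genes higher by the mean response 48.2% were higher with AF10 deletion there (45.5% and 51.4% in replicates 1 and 2), and of genes lower 55.6% were lower. All 4 transgene factors had a lower mean in each other day 4 group than in Day4_fl_DMSO. Pou5f1 had 134 CPM there, 106 in Day4_fl_SGC, 97.8 in Day4_creAF10_DMSO and 92.1 in Day4_creAF10_SGC. Whether this bears on the shared genes was not tested.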

How the results depend on the processing

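The alternatives fixed in advance were DESeq2 size factors, no filter, a mean of at least 5 CPM, the replicate block, an estimated correlation, DESeq2, only the libraries compared, and leaving out each replicate; the replicate block per stage (paired fit) was chosen after the data had been seen. DESeq2 size factors and no filter left each count within 1.5 times. Counts of calls depended on how the replicate numbers were handled and on single libraries. Leaving out a library assumes that the lone one varies like the other groups. It was done without a block, which sets 1 replicate against the mean of both, so calls lost that way also carry the difference between replicates. Within replicate pairs, a check added later, 6 of the 7 gene results that turned kept 1 sign, the exception being Klf4 (-0.07 and 0.38). Those 6 were named because the paired fit called them, which favours like changes in both pairs, so their kept sign is no support. The medians of 17 of the 18 list tests kept 1 sign too. The exception was the interferon response list for AF10 deletion in SGC0946 (-0.01 and 0.29). Where the cause is not named, the cause was not tested.

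With the replicate block, calls (higher, then lower) were 0 and 6 for AF10 deletion in MEFs, 0 and 1 on day 4 in DMSO, 559 and 247 for SGC0946 in fl cells, 71 and 22 in AF10-deleted cells, 714 and 402 for both together and 1 and 0 for the interaction, with 1 gene shared by the deletion and SGC0946. With the replicate block per stage they were, in this order, 17 and 117, 469 and 470, 1480 and 990, 736 and 344, 1714 and 1289, and 10 and 45, with 569 shared; AF10 deletion in SGC0946 gave 10 and 14, and its effect on day 4 against MEFs 130 and 31. DESeq2 called 1 and 19 for AF10 deletion in MEFs, 9 and 4 on day 4 in DMSO, 218 and 85 for SGC0946 in fl cells, 32 and 15 in AF10-deleted cells, 2 and 0 for the deletion in SGC0946, 305 and 184 for both together, 1 and 1 for the interaction and 2 and 0 for day 4 against MEFs, with 10 shared. With only the libraries compared, SGC0946 called 264 and 69 in fl cells and 34 and 5 in AF10-deleted cells, and both together 416 and 146. A mean of at least 5 CPM, which tests fewer genes, left 21 lower for SGC0946 in fl cells and 119 and 47 for both together.

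Without 1 replicate, SGC0946 in fl cells kept 1 to 5 calls higher and 0 lower, SGC0946 in AF10-deleted cells 0, and both together 1 to 5 higher and 0 to 3 lower. AF10 deletion, the interactions and the shared calls stayed at 0. Day 4 against MEFs gave 2664 to 3065 higher and 2675 to 3211 lower in fl cells, and 2936 to 3326 and 2919 to 3436 in AF10-deleted cells. Of the 18 list tests passed, 0 passed with an estimated correlation, with the replicate block or without; 50 passed with the replicate block per stage, and 0 of these with an estimated correlation. Without 1 replicate, the camera adjusted p of the interferon response list for AF10 deletion in SGC0946 ran from 1.02e-08 to 0.714, the latter with the direction turned, Fos on day 4 in DMSO from -0.19 to 1.80 and Dusp1 from -0.04 to 1.03, Nr4a1 in SGC0946 from -0.01 to 1.07, and the interaction of Dusp1 from -1.02 to 0.06, with 0.02 without Day4_fl_SGC replicate 2. Against MEFs, the deletion effect of Fos ran from -0.20 to 1.79 and that of Dusp1 from -0.02 to 1.05, and Klf4 on day 4 against MEFs from -0.01 to 0.32. Of the list tests with 1 replicate left out, 57 kept their call and 26 lost it. The 18 list tests also passed with the replicate block and with the block per stage. Of 163 results for named genes, 20 more passed with the replicate block and 108 more with the block per stage. Many of the 108 were named because that last fit called them, so their passing there is no support. Leaving out replicates turned the direction of 8 values of named genes. Whether a call was kept is no measure there, since most of these results had no call in the first fit to lose.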

Other observations

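In MEFs the metallothionein genes Mt1 and Mt2, which are often induced together, differed after AF10 deletion: Mt1 went from 91.2 ± 42.6 to 466 ± 122 CPM (SD, n = 2 per group), while Mt2 went from 62.9 to 75.8 CPM and missed the threshold in the paired fit (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.442). Mt2 lies outside the rule for named genes and was chosen after its values had been seen.

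The summed CPM of the Y-linked genes in replicate 2 was 0.386% of that in replicate 1 in MEF_fl, 0.127% in MEF_creAF10, 0.868% in Day4_fl_DMSO, 0.5% in Day4_fl_SGC, 0.708% in Day4_creAF10_DMSO and 0.563% in Day4_creAF10_SGC. Day 4 cells were grown on feeder MEFs, whose sex the labels do not give.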
